A study of Caenorhabditis elegans with 9 samples.

How the data were processed

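Whole animals of Caenorhabditis elegans were profiled on NimbleGen one-colour arrays labelled with Cy3, with 9 arrays in 3 groups of 3: wild type, the daf-9 mutant and the daf-12 mutant. Per the labels, each array held RNA of a separate culture grown to the fourth larval stage at 20 °C and then kept for 24 h with Pseudomonas aeruginosa, and about 5 µg of RNA was used. Groups and replicate numbers were taken from the sample labels. No slide, hybridisation day or other batch was given in the sources used here, so genotype and any such batch cannot be told apart. No scanner output and no uninfected animals were analysed here.

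The authors deposited 1 table of intensity values on a linear scale, and the submitters' processing notes name RMA (robust multi-array average), the only tool they name. The background, normalization and summarization settings, the software version and the annotation release are not given in the sources used here. The linear scale was read from the values, which ran from 100.05 to 60837 with array medians between 960.4 and 979.7. Of 33458 rows, 19759 were empty on all 9 arrays and 13699 had a value on every array. None of the 13699 held a value below 100, while 293 had a lowest value under 110, so the rows appear to have been limited at 100 on every array, a step no source states. A transcript that is bright in 1 genotype and under that level in another would then be missing, which affects counts of large changes in both directions. As it is usually run, RMA brings the arrays to a common distribution, so a change in the total RNA of an animal would not be seen. For arrays, their number limits the precision.

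Rows carry a WormBase gene identifier, a symbol and a sequence name. Symbols were updated through a reference gene table of assembly WBcel235, used for names alone. Of the rows with values, 13451 (98.2%) matched, covering 11354 genes, and 248 kept the name of the table. The symbol of 398 rows had changed, and 14 older symbols now belong to another gene. For 1692 genes with several measured rows, the row with the highest mean over the 9 arrays stood for the gene. Called rows of a gene differed in direction for 20 genes in the daf-9 mutant, 23 in the daf-12 mutant and 3 between the mutants. Probe sequences were not used here, so signal shared among close paralogs, such as the major sperm proteins, vitellogenins, hsp-16 genes and collagens, could not be separated. None of the 5355 rows of piwi-interacting RNAs had a value.

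The log2 of each intensity was taken with no pseudocount. Group means of all 9 arrays were fitted in 1 model with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which shares the estimate of spread among groups, with 6 residual degrees of freedom per row. Each mutant was compared with wild type, both mutants together with wild type, and the mutants with each other, and an F test covered any difference among genotypes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 13699 rows, with a threshold of 0.05. Counts with at least a 2-fold change are given beside these. An exact permutation test of 3 arrays against 3 allows no p under 0.1.

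Gene lists fixed beforehand covered immunity, stress, detoxification, hormone and dauer signalling, metabolism, germ line, cuticle, housekeeping complexes and markers of tissues. Of 39 lists, 38 had at least 3 measured members. They were tested with camera in limma over 1 row per gene with a preset correlation of 0.01, adjusted over the 38 lists of a comparison, and again with an estimated correlation and with fry. Counts adjusted over the list alone used the members' own p-values. Several genes belong to more than 1 list, among them gst-4, mtl-1, the hsp-16 genes, clec-60 and lin-41.

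The design, the tests, the gene lists, the alternatives and the rule for named genes were set before the data were examined. The rule took daf-9 and daf-12. For each comparison it took the 10 highest and 10 lowest genes past the threshold whose groups did not overlap, with at most 3 per gene family. It took the 4 members of each described list with the smallest p, the 5 highest and 5 lowest shared changes, and allowed further members of a list beside the list's count. Those further members, and the genes that changed in opposite directions in the mutants, were chosen after their values were seen. T14B1.1 and srlf-30 belong to no list.

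Comparisons that share the wild-type arrays were set against 50 simulations of unchanged groups. Alternatives were a second quantile normalization, arrays centred on their medians, omission of the dimmest 25% of rows and rows of a gene averaged. Others were only the compared groups in the fit, array weights, and an intensity trend with a robust prior. A test without moderation used only the arrays compared, with the mutants as a single group where both were set against wild type. A 2-fold minimum, the replicate number as a block and each array left out in turn completed the alternatives. A slide block was listed too and was not run because no slide was given. Versions of the list counts in other splits of the arrays, with an estimated correlation and on residuals, were chosen after seeing the data.

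The fit was tested on simulated data for 13699 rows with 200 of them changed. For the daf-9 mutant against wild type, it recovered 58% of changes of 1.25-fold, 96% of 1.5-fold and 100% of 2-fold and 4-fold, and 11 of 188 calls (5.85%) were false. For the daf-12 mutant against wild type, the shares were 40%, 98%, 100% and 100%, and 13 of 182 calls (7.14%) were false. For the daf-12 mutant against the daf-9 mutant, they were 50%, 100%, 100% and 100%, and 8 of 183 calls (4.37%) were false. In the list test over 11354 genes, with 1 list shifted by 0.5 on the log2 scale, 1 of 38 lists was called. Names were matched and figures drawn in python 3.11.15.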

Results

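Transcript levels were measured on 9 one-colour microarrays of whole Caenorhabditis elegans. The animals were wild type, daf-9 mutants of allele e1406 or daf-12 mutants of allele rh411rh61, with 3 arrays per genotype, each from a separate culture. All cultures were grown to the fourth larval stage (L4) at 20 °C and then infected for 24 h with Pseudomonas aeruginosa, a bacterial pathogen that kills worms through the intestine. No uninfected culture was analysed here, so every difference is one between genotypes under infection. DAF-9 is a cytochrome P450 that makes dafachronic acids, the steroid hormones that bind the nuclear receptor DAF-12. The comparisons ask how loss of the hormone-making enzyme and mutation of its receptor change expression, and whether both change the same genes. Of 33458 rows in the table, 13699 held values, and these were intensities from RMA, a summary of an array's probes per transcript, between 100.05 and 60837 with array medians from 960.4 to 979.7. The other 19759 were empty on every array and entered no comparison, and the reason for leaving them empty is not given in the sources used here. The lowest value among the 13699 was just above 100, so genes near or under that level could not be compared. The number of arrays limits the precision of each value.

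Arrays of a genotype correlated at r = 0.994 to 0.997 across rows, and arrays of different genotypes at 0.960 to 0.978. The first principal component held 60.6% of the variance and placed the daf-12 mutant between wild type and the daf-9 mutant. The second held 25.2% and set the daf-12 mutant apart from both. By the F test of limma, 9548 of 13699 rows differed among the 3 genotypes at an adjusted p below 0.05. The median residual SD was 0.10 on the log2 scale.

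The level of the mutated genes was examined first. Both rows of daf-9 were empty on all arrays, so its level is unknown here. Of 4 daf-12 rows, 3 were measured (transcripts of F11A1.3), and all 3 were higher in the daf-9 mutant than in wild type. The brightest row stood at 10.71 ± 0.02 in wild type, 10.99 ± 0.10 in the daf-9 mutant and 10.34 ± 0.14 in the daf-12 mutant (log2 intensity, mean ± SD, n = 3 each). Its log2 fold change was 0.28 in the daf-9 mutant (limma adjusted p = 0.0095) and -0.37 in the daf-12 mutant (limma adjusted p = 0.0019). The other rows gave 0.68 and 0.64 in the daf-9 mutant, and -0.09 and -0.26 in the daf-12 mutant, of which -0.09 did not pass (limma adjusted p = 0.37). The labels do not say what the allele does to the transcript, so these levels do not check the genotype. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1.

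In the daf-9 mutant, genes for the moulting cycle, the cuticle, C-type lectins and sperm were lower than in wild type, and genes of germline proliferation were higher. Vitellogenins, the yolk proteins, also stood higher. At an adjusted p below 0.05, 4664 rows rose and 3291 fell, together 7955 of 13699. The arrays of the groups did not overlap in 8668 rows, or 63.3%, where chance gives 10%. Most changes were small, and 83 rows rose and 754 fell by at least 2-fold. The strongest rises were in the cuticle collagens col-102 (log2 fold change 3.83 ± 0.08 SE) and col-108 (3.51 ± 0.10). Next came F16B4.7 (3.18), scl-5 of the SCP/TAPS secreted proteins (3.11), Y41G9A.10 (2.96), the lipase-family gene lips-15 (2.93) and pqn-75 (2.78). The uncharacterised genes F35F10.13 (2.51) and T13F3.6 (2.07) and the glutathione S-transferase gst-4 (1.99) completed the 10 highest. The deepest falls were in ZK1025.3 (-3.30), ZK1025.2 (-3.14) and W08E12.2 (-2.86). The C-type lectin clec-60 (-2.62), mltn-1 (-2.26), Y102A11A.5 (-2.18), E01G4.6 (-2.14), Y53F4B.27 (-2.14), K01D12.9 (-2.13) and the hedgehog-related wrt-6 (-2.11) followed. All 20 had adjusted p values of 7.8e-10 or less by limma. ZK1025.2 and ZK1025.3 have neighbouring names, and whether their probes tell related transcripts apart was not examined here.

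Among moulting and apical cuticle genes, 24 of 27 measured members were lower and none was higher in the daf-9 mutant, with a median log2 fold change of -1.26 (camera adjusted p = 2.7e-12). Examples were nas-6 (-1.90), an astacin protease, lpr-3 (-1.54), a lipocalin of the apical matrix, and ptr-4 (-1.59), a patched-related gene. Adjusted over the list alone, the count was also 24. Of 131 cuticle collagens, 83 fell and 17 rose, with a median of -0.53 (camera adjusted p = 1.5e-10). Falls included sqt-1 (-2.02), col-90 (-1.98) and bli-1 (-2.04), while col-102, col-108, col-123 (1.78) and col-33 (1.53) went the other way. Adjusted over the list alone, 84 collagens fell and 18 rose. The collagen and moulting lists held their calls with an estimated correlation (adjusted p = 0.0075 and 0.0059).

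Sperm and germline genes moved in opposite directions in the daf-9 mutant. Of 23 sperm and spermatogenesis genes, 21 were lower and 1, the sperm-fate regulator fog-1 (0.65), was higher, with a median of -0.74 (camera adjusted p = 8.2e-09, and 0.0078 as the adjusted p with an estimated correlation). They included fer-1 (-1.27), needed for fusion of sperm organelles, spe-4 (-1.24), a presenilin of spermatocytes, and spe-41 (-1.04), a sperm calcium channel. Adjusted over the list alone, 22 were called. Major sperm proteins, the cytoskeletal proteins that move worm sperm, fell in 29 of 30 rows with a median of -0.46 (camera adjusted p = 1.7e-09), a call lost with an estimated correlation (adjusted p = 0.076). These paralogs are near-identical, so their rows may not be independent measurements. Germline proliferation, meiosis and P granule genes rose in 32 of 34 cases with none lower, at a median of 0.31 (camera adjusted p = 9.0e-06, and 0.017 as the adjusted p with an estimated correlation). Examples were the Argonaute csr-1 (0.62), the translational repressors fbf-1 (0.52) and fbf-2 (0.51) and the cohesin rec-8 (0.49). Oocyte and eggshell genes rose in 24 of 35, among them gld-1 (0.52) and oma-2 (0.41) (camera adjusted p = 0.0012), a call lost with an estimated correlation (adjusted p = 0.064). All 6 vitellogenins were higher, from vit-6 (0.28) to vit-3 (1.37), and this list gave a camera adjusted p = 0.0014 and an adjusted p = 0.052 with an estimated correlation. Without moderation the call of vit-6 was lost (adjusted p = 0.0611). There were 29 major sperm proteins, 32 germline genes, 24 oocyte genes and 6 vitellogenins called when p was adjusted over the list alone.

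Immune and detoxification genes of the daf-9 mutant split by family. C-type lectins, many of them induced by pathogens, fell in 49 of 76 and rose in 12, at a median of -0.40 (camera adjusted p = 1.6e-07, and 0.0059 as the adjusted p with an estimated correlation). Besides clec-60, these included clec-13 (-1.95), clec-17 (-1.38) and clec-45 (-1.24). Effectors that depend on the p38 MAP kinase PMK-1, the main immune kinase of the worm intestine, were lower in 14 of 20 and higher in 4, with irg-6 at 0.49. This list was called with the preset correlation (camera adjusted p = 0.0032) and not with an estimated one (adjusted p = 0.052). Its members included irg-5 (-0.72), clec-4 (-0.67) and F01D5.5 (-0.81). Of 9 lysozymes, 4 fell, among them lys-7 (-1.51), and 2 rose, ilys-3 (1.73) and ilys-2 (0.99). The median was -0.20, and the list itself was not called (camera adjusted p = 0.44). Glutathione S-transferases were higher in 13 of 25 and lower in 1 (gst-22, -0.32), led by gst-4, gst-19 (1.52) and gst-10 (0.90), with a camera adjusted p = 0.024 and an adjusted p = 0.079 with an estimated correlation. The call of gst-22 was lost with a second quantile normalization (limma adjusted p = 0.0619), without moderation (0.141), and without wild type replicate 1 (0.0772) or daf-9 mutant replicate 3 (0.0745). The metallothionein mtl-1 rose (1.88). Ribosomal proteins (20 of 80 higher, 1 lower, which was rpl-42 at -0.99, adjusted p = 0.052 with an estimated correlation) and proteasome subunits (15 of 32 higher, adjusted p = 0.075 with an estimated correlation) showed small rises. Both were called with the preset correlation alone. Without the dimmest 25% of rows, the glutathione S-transferase list gave an adjusted p = 0.081 and the proteasome list 0.051 with the preset correlation. Adjusted over the list alone, 63 lectins, 18 p38-dependent effectors, 7 lysozymes, 14 glutathione S-transferases, 17 ribosomal proteins and 11 proteasome subunits were called. Markers of intestine (median -0.07), muscle (-0.13) and neurons (0.09) were not called as lists.

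**Figure D1:**
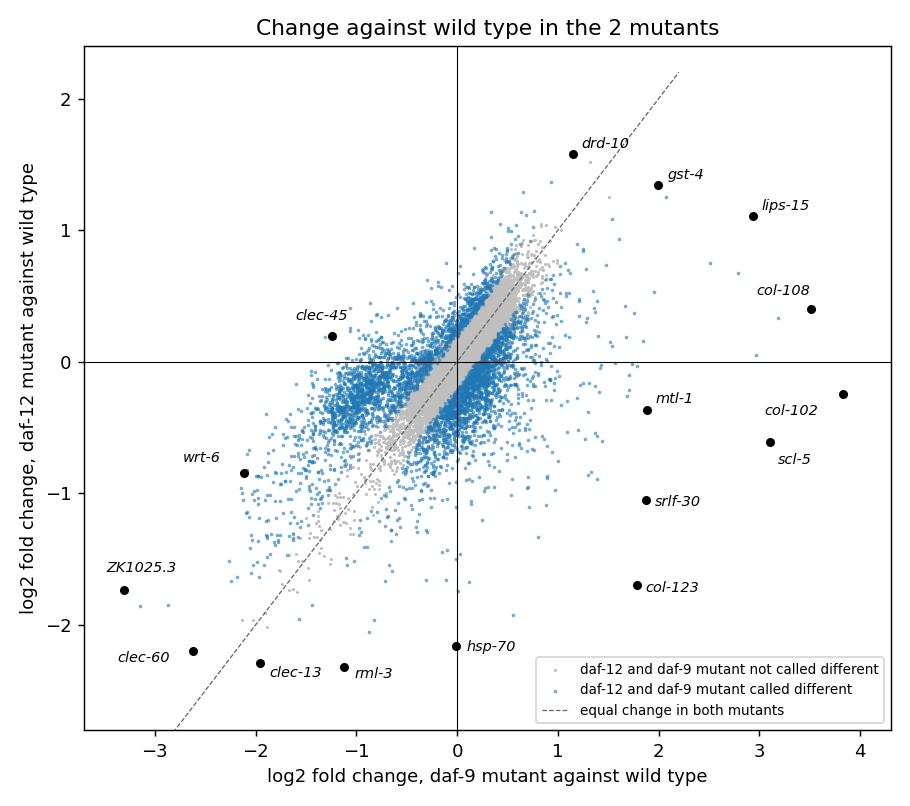
Each point is one row of the array, placed by its log2 fold change against wild type in the daf-9 mutant (horizontal) and the daf-12 mutant (vertical), blue where limma called the 2 mutants different. The collagens col-102 and col-108 lie at 3.83 and 3.51 on the daf-9 axis and at -0.24 and 0.40 on the daf-12 axis, while hsp-70 lies at -0.01 and -2.16.

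In the daf-12 mutant, moulting genes and C-type lectins were lower as well, and inducible heat shock genes and targets of the stress factor DAF-16 were lower too. Germline and oocyte genes were higher. In all, 4200 rows rose and 3426 fell at an adjusted p below 0.05, together 7626 of 13699, and 22 rose and 217 fell by at least 2-fold. The highest were drd-10 (log2 fold change 1.58 ± 0.08 SE), F36F12.4 (1.52), the collagens col-95 (1.36) and col-96 (1.14), and gst-4 (1.35). The nuclear envelope gene lem-2 (1.29), Y54E10A.6 (1.14) and reps-1 (1.14) followed, with T13F3.6 and C50E3.12 between lem-2 and Y54E10A.6. The lowest were rml-3 (-2.32), clec-13 (-2.29), clec-60 (-2.20) and hsp-70 (-2.16 ± 0.08 SE). F14F3.4 (-2.05), the lipocalin-related lpr-4 (-2.01), Y37A1B.7 (-1.96), the glucuronosyltransferase ugt-57 (-1.95), C05G5.7 (-1.93) and wrt-10 (-1.91) followed. Of all 20, reps-1 had the highest adjusted p by limma (3.5e-05).

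Of 24 heat shock and unfolded protein response genes, 13 fell and 3 rose in the daf-12 mutant (median -0.26, camera adjusted p = 0.0012, and 0.036 as the adjusted p with an estimated correlation). The falls included the stress-inducible chaperones hsp-16.2 (-1.74), hsp-16.41 (-1.68), hsp-16.48 (-1.66), hsp-70 and the hsp-70-like F44E5.4 (-1.43), whereas the mitochondrial chaperones hsp-6 (0.34) and hsp-60 (0.31) and the heat shock factor hsf-1 (0.35) rose. The call of hsp-60 was lost without wild type replicate 2 (limma adjusted p = 0.0749) or daf-12 mutant replicate 3 (0.0781). Without moderation of the variance, adjusted p was 0.0577 for hsp-6, 0.153 for hsp-60 and 0.0547 for hsf-1. The hsp-16 genes are close paralogs and may share signal. Genes that DAF-16 raises were lower in 17 of 22 (median -0.39, adjusted p = 0.036 with an estimated correlation), a list that also holds hsp-16 genes and includes dod-3 (-1.08). Fat metabolism genes fell in 18 of 36, with acs-2 (-1.11), an acyl-CoA synthetase of fat oxidation, and the lipase lipl-1 (-1.03) among them (adjusted p = 0.027 with an estimated correlation). Nuclear hormone receptors were lower in 47, higher in 15 and not called in 57 (adjusted p = 0.027 with an estimated correlation), with nhr-21 at -1.35 and nhr-17 at -0.84. Genes called when adjusted over the list alone were 16 heat shock, 19 DAF-16-raised, 18 fat metabolism and 60 receptor genes.

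Moulting genes fell in 25 of 27 cases in the daf-12 mutant at a median of -0.98 (camera adjusted p = 5.1e-16, and 0.0028 as the adjusted p with an estimated correlation), with ptr-4 at -1.75, lpr-3 at -1.52 and mlt-9 at -1.47. Collagens divided into 57 lower and 28 higher of 131, and their list call was lost with an estimated correlation (adjusted p = 0.065). The cuticle-shaping collagens dpy-7 (-1.45) and dpy-8 (-1.24) were among those that fell. Germline genes rose in 31 of 34 (median 0.35, adjusted p = 0.014 with an estimated correlation), including rec-8 (0.55) and msh-5 (0.59). Oocyte and eggshell genes rose in 29 of 35 (adjusted p = 0.027 with an estimated correlation), including gld-1 (0.63) and mex-1 (0.53). Sperm genes fell in 8 of 23 (median -0.15) and the list was not called (camera adjusted p = 0.058). Major sperm proteins fell in 6 of 30 (camera adjusted p = 0.025, and 0.37 as the adjusted p with an estimated correlation). That preset call was also lost without daf-12 mutant replicate 1 (adjusted p = 0.057) or replicate 2 (0.053), and adjusted over the list alone 0 were called by limma, against 6 over all genes. Vitellogenins fell in 3 of 6, led by vit-6 (-0.46), with no list call (camera adjusted p = 0.099). Adjusted over the list alone, 25 moulting genes, 86 collagens, 32 germline, 30 oocyte and 7 sperm genes and 4 vitellogenins were called.

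C-type lectins fell in 41 of 76 in the daf-12 mutant (median -0.26, adjusted p = 0.0086 with an estimated correlation). The p38-dependent effectors fell in 9 of 20 and rose in 4 (camera adjusted p = 0.023, and 0.079 as the adjusted p with an estimated correlation), with irg-5 and irg-4 (-0.63) among the lower. Components of the p38 pathway were lower in 11 of 19 and higher in none, a preset call (camera adjusted p = 0.013) that an estimated correlation did not keep (adjusted p = 0.065). They included the adaptor tir-1 (-0.45), the kinase pmk-2 (-0.45) and svh-1 (-1.19), a growth-factor-like gene of the related JNK pathway. CUB-like and downstream-of-DAF-16 genes fell in 9 of 17, and saposin-like proteins in 11 of 17 (adjusted p = 0.047 for each with an estimated correlation). spp-13 (-1.32) fell, whereas spp-17 (1.09) rose. Intestine markers were lower in 10 of 24 and neuron markers in 6 of 18 (camera adjusted p = 0.028 and 0.029), calls that were lost with an estimated correlation (adjusted p = 0.085 and 0.087). Both measured thaumatin genes, thn-1 (-1.17) and thn-2 (-1.01), were lower, too few for a list test. In the daf-9 mutant both were lower as well, at -1.21 and -1.19. CUB-like genes fell there in 10 of 17 (camera adjusted p = 0.027, and 0.085 as the adjusted p with an estimated correlation). The p38 pathway list fell there in 5 of 19 without a call (camera adjusted p = 0.22), and its lowest member stood at -1.18. In the daf-12 mutant, adjusted over the list alone, 48 lectins, 13 effectors, 11 pathway components, 10 CUB-like, 15 saposin-like, 10 intestine and 7 neuron genes were called.

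**Figure D2:**
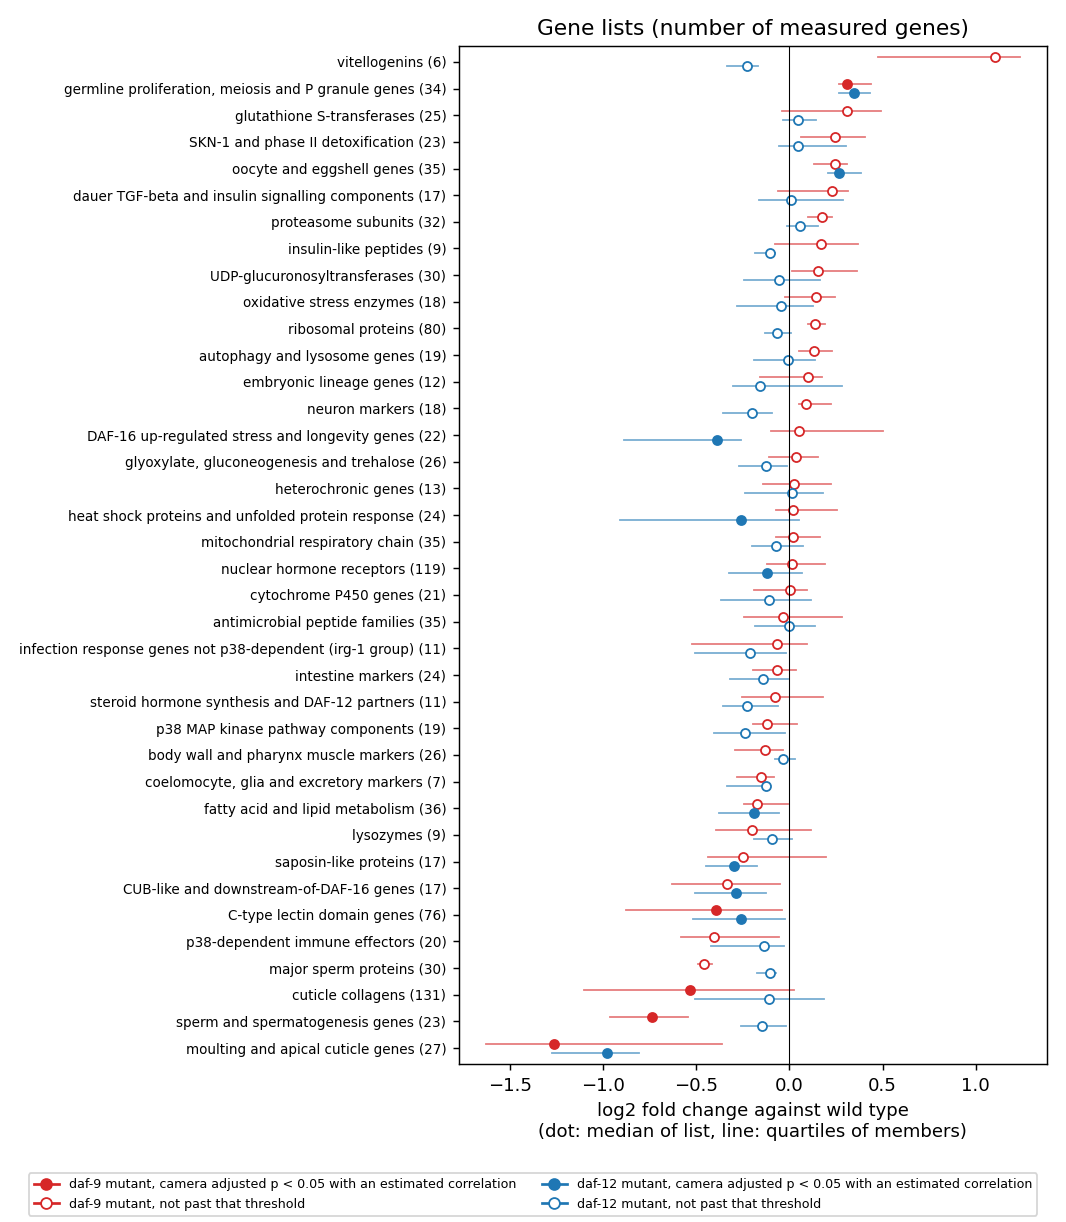
Dots give the median log2 fold change against wild type of each of the 38 tested gene lists in the daf-9 (red) and daf-12 (blue) mutant, lines the quartiles of its members, and filled dots mark lists past an adjusted p of 0.05 with an estimated correlation. Of these lists, moulting genes lie lowest in both mutants (-1.26 and -0.98), while DAF-16-raised genes (0.05 and -0.39) and heat shock genes (0.02 and -0.26) lie apart between the mutants.

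The mutants were then compared directly. Relative to the daf-9 mutant, the daf-12 mutant had lower vitellogenin, heat shock, ribosomal protein and neuronal transcripts, and higher sperm and collagen transcripts. 2298 rows were higher and 2107 lower, together 4405 of 13699, with 136 at least 2-fold in each direction. The small majority of higher rows turned with another scaling, to 2148 higher and 2275 lower after a second quantile normalization and to 2123 and 2356 with arrays centred on their medians. The largest differences were in col-102 (log2 fold change -4.08 ± 0.08 SE), scl-5 (-3.72), col-123 (-3.48), col-108 (-3.11), srlf-30 (-2.92), Y41G9A.10 (-2.91) and F16B4.7 (-2.84). Lower by less were C05G5.7 (-2.48), dach-1 (-2.27), listed under an older cytochrome P450 symbol, and mtl-1 (-2.24). On the higher side stood ZK1025.3 (1.57), the collagen rol-1 and ule-2, both just below it, the claudin-like clc-12 (1.47), clec-45 (1.44) and col-65 (1.43). bus-28 (1.40), col-175 (1.38), Y45F10C.4 (1.35) and clec-260 (1.33) completed the 10 highest.

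All 6 vitellogenins were lower in the daf-12 than in the daf-9 mutant, with vit-3 at -1.56 and vit-5 at -1.47 (median -1.15, adjusted p = 0.0087 with an estimated correlation). Heat shock genes were lower in 15 of 24 (median -0.34, adjusted p = 0.0063 with an estimated correlation), with hsp-70 at -2.14 and hsp-16.41 at -1.79. DAF-16-raised genes were lower in 17 of 22 (adjusted p = 0.0087 with an estimated correlation), including dod-3 (-1.96) and the histone H1-like hil-1 (-1.63). Sperm genes were higher in 20 of 23 (median 0.62, adjusted p = 0.0063 with an estimated correlation), with fer-1 at 1.02 and spe-4 at 0.92. Major sperm proteins were higher in 29 of 30, but the list call was lost with an estimated correlation (adjusted p = 0.081). Collagens were higher in 79 and lower in 8 of 131 (adjusted p = 0.0063 with an estimated correlation), whereas the moulting list did not differ by its test (median 0.02, camera adjusted p = 0.67). Within it, wrt-6 (1.27) and mlt-10 (0.88) were higher and pan-1 (-0.66) was lower. Ribosomal proteins were lower in 35 of 80 at a median of -0.20 (adjusted p = 0.0063 with an estimated correlation), with rps-15A at -0.45, while rpl-42 was higher (0.88). Neuron markers were lower in 9 of 18 (adjusted p = 0.019 with an estimated correlation). They included sbt-1 (-0.75) and egl-21 (-0.64), both of neuropeptide processing, and the neuropeptide gene flp-1 (-0.65). Glutathione S-transferases (9 of 25 lower), glucuronosyltransferases (15 of 30) and nuclear hormone receptors (34, with 6 higher) were lower too (adjusted p = 0.045, 0.045 and 0.0096 with an estimated correlation). Germline and oocyte lists were not called between the mutants (camera adjusted p = 0.76 and 0.58). Between the mutants, adjusted over the list alone, 16 heat shock, 19 DAF-16-raised, 22 sperm, 94 collagen, 40 ribosomal protein and 9 neuron genes were called.

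**Figure D3:**
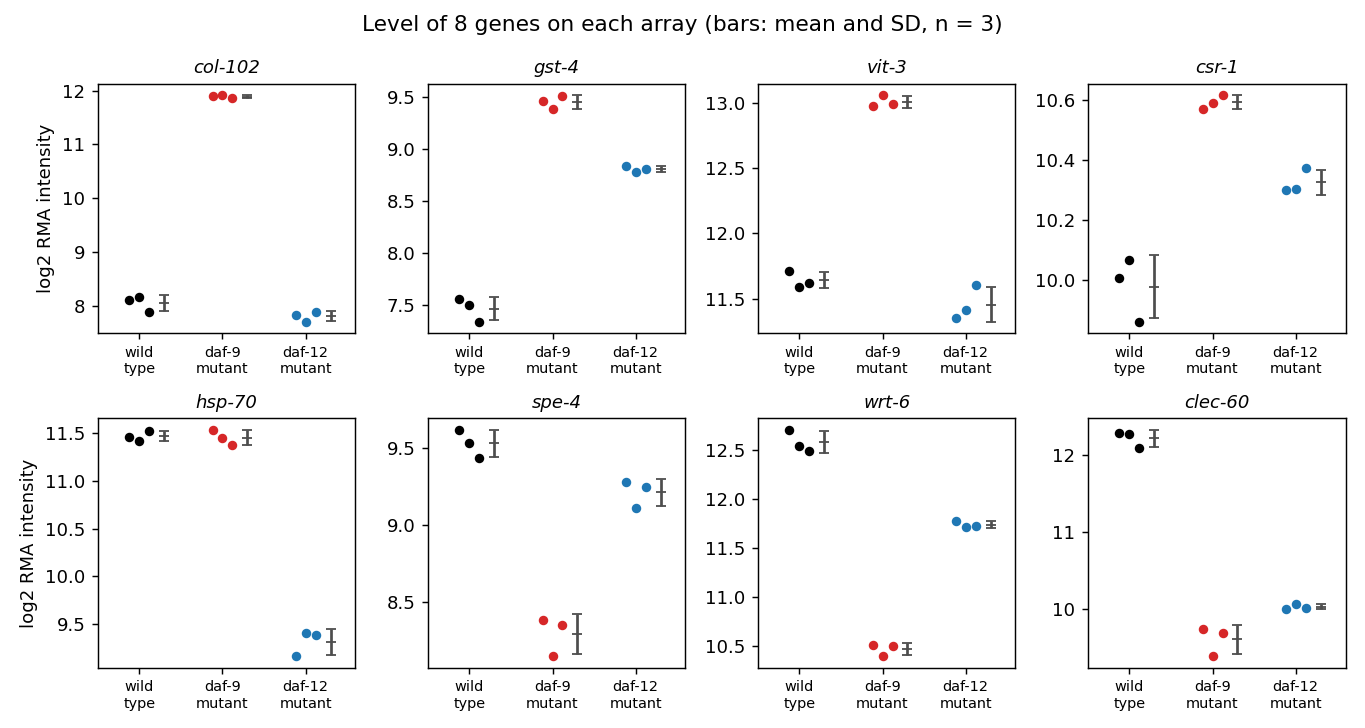
Points are the log2 RMA intensities of 8 genes on each of the 9 arrays, with the mean and SD of the 3 arrays beside them, and each panel has its own vertical scale. col-102 and vit-3 stand high in the daf-9 mutant (11.89 ± 0.03 and 13.01 ± 0.04), and hsp-70 stands low in the daf-12 mutant (9.31 ± 0.14 against 11.47 ± 0.05 in wild type).

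Many genes changed in the same direction in both mutants. Shared rises covered 3158 rows and shared falls 2163, where independent lists would share 1430 and 823, and 286 rows were called in opposite directions where 2175 would be. Across rows, which are not independent replicates, the log2 fold changes of the mutants correlated at r = 0.67. Both comparisons use the same 3 wild-type arrays, and simulated unchanged groups gave r = 0.50 from the shared controls alone, so r by itself shows little. The covariance was 0.120 against a simulated 0.00397, so random spread of the shared controls gave a small part of it. In the 50 simulations at most 0 rows were called in the same direction in both comparisons, though these groups held no real change. A batch that set the wild-type arrays apart was not simulated. The controls were not split between the comparisons, since 3 arrays do not leave 2 for each. By the mean of both changes, the highest shared rises were lips-15 (2.93 in the daf-9 and 1.11 in the daf-12 mutant), col-108 (3.51 and 0.40), F16B4.7 (3.18 and 0.34), pqn-75 (2.78 and 0.68) and gst-4 (1.99 and 1.35). By the same mean, the deepest shared falls were ZK1025.3 (-3.30 and -1.73), ZK1025.2 (-3.14 and -1.86), clec-60 (-2.62 and -2.20), W08E12.2 (-2.86 and -1.85) and clec-13 (-1.95 and -2.29). The rise of F16B4.7 in the daf-12 mutant was lost without wild type replicate 2 (limma adjusted p = 0.101) or daf-12 mutant replicate 1 (0.0950), and without moderation it gave 0.136, against 0.101 for col-108. With both mutants averaged, 8598 rows differed from wild type, 4849 higher and 3749 lower.

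Of 39 gene lists, 38 had at least 3 measured members. With the preset correlation, camera called 14 in the daf-9 mutant, 17 in the daf-12 mutant and 18 between the mutants, and with an estimated correlation 5, 10 and 10 of these held. Other splits of the arrays, which mixed the genotypes, called 7 to 13, 5 to 15 and 7 to 13 lists with the preset correlation, and 0 in each with an estimated one. Such splits still carry differences between genotypes. On residuals, with the mean of each genotype removed, they called 0, 0 and 0 to 2 lists with the preset correlation.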

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

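The tests of scaling for the moulting and heat shock genes were chosen only after the result was seen. So were those of other moult-cycling families, of a single developmental course, and of chaperones and handling. The versions of the list counts in other splits with an estimated correlation and on residuals were chosen then too.

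A group of 253 genes was called in opposite directions in the mutants and also differed between them by limma's direct test. Of these, 210 were higher in the daf-9 and lower in the daf-12 mutant and 43 the reverse. Changes called in opposite directions add up in the difference between the mutants, so the direct test adds little support. Over all rows, 286 were called in opposite directions, where independent calls would give 2175. The collagen col-123 had a log2 fold change of 1.78 in the daf-9 and -1.70 in the daf-12 mutant, a difference of -3.48 (adjusted p = 2.8e-10). For srlf-30 the values were 1.87 and -1.05, and the difference was -2.92. The cytochrome P450 gene dach-1 stood at 1.38 and -0.89, a difference of -2.27. T14B1.1 stood at 0.97 and -0.97, a difference of -1.94. dod-3 stood at 0.88 and -1.08, a difference of -1.96. No outlier test of single values was applied to groups of 3 arrays.

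A shift common to all rows did not explain the lower moulting genes in both mutants. Their median lay -1.35 from that of all rows in the daf-9 mutant and -1.01 in the daf-12 mutant. Since the array medians were already nearly equal, these values largely restate the falls of the list and do not decide on scaling of other kinds. Wild type still larval and mutants already adult was argued against by the adult-stage collagens col-7, col-19 and col-62. Their median log2 fold change in the daf-9 mutant was -0.20 and not above 1. In the daf-12 mutant they stood at 0.22, 0.30 and 0.17, also below 1, and col-62 was not called there (limma adjusted p = 0.0898). They were already bright in wild type (intensities of 8956, 21280 and 12201). These genes therefore cannot show a difference in age after they come on, which stays open. A single course shared by both mutants was not decided. The daf-12 change as a share of the daf-9 change differed by 57.3 percentage points between moulting and sperm genes. But genes of different tissues need not change in equal proportion along a course, so this difference does not argue against it. Wild-type animals nearer to a moult remain a candidate explanation, with 39 other genes of moult-cycling families at a median of -0.96 in the daf-9 mutant, but a weaker -0.38 in the daf-12 mutant, where the moulting list itself stood at -0.98. A direct effect of hormone signalling on these genes was not tested and stays open.

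A shift common to all rows did not explain the lower heat shock genes of the daf-12 mutant, since hsp-70 and 4 hsp-16 genes lay at a median of -1.71 from all rows. But these genes were picked after their falls were seen, and the array medians were already nearly equal. The value thus largely restates the falls and does not decide on scaling of other kinds. A fall of the whole list by a similar amount was not seen, as its other 19 members had a median of -0.0928. They were set apart after the falls were seen, which raises that median, and they include regulators such as hsf-1 besides chaperones. F44E5.4 (-1.43), hsp-17 (-0.74) and pek-1 (-0.67) were among those that fell, while only hsp-6, hsp-60 and hsf-1 rose. The falls were thus not confined to hsp-70 and the hsp-16 genes. Warming or handling of the cultures cannot be told apart from genotype, because cultures of a genotype may have been handled together; the range over the arrays of a group had a median over these genes of 0.166 on the log2 scale in the most variable group. An effect of the daf-12 genotype stays open and was not tested.

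Of 2-fold changes against wild type, 754 of 837 were lower in the daf-9 mutant. The lower limit of the deposited intensities did not account for this among the brightest 25% of rows, where 94 were lower and 3 higher, or 96.9% lower. The dimmer rows, which held most of these changes, were not tested in this way. Genes under the limit in a genotype would be missing, so its part in the whole share stays open. With arrays centred on their medians 89.7% were lower. The array medians already lay between 960.4 and 979.7, so centring could hardly have changed the share and does not decide on scaling. A biological cause of the higher level of these genes in wild type stays a hypothesis, because the pattern was found and tested on the same data. A batch that followed genotype stays open as well.

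Other splits of the arrays were counted for each comparison. For rows called, the 10 splits of 6 arrays are too few for a share under 0.05, and the real split against the highest other gave 7955 and 0 in the daf-9 mutant, 7626 and 0 in the daf-12 mutant, and 4405 and 0 between the mutants. The same limit holds for lists called with the preset correlation, 14 against 13, 17 against 15 and 18 against 13. Those other splits mixed the genotypes, and on residuals, with genotype means removed, their highest counts were 0, 0 and 2. In a fit of only wild type against the other 6 arrays, 1 of 84 splits, the real one, reached 6312 rows, a share under 0.05. The highest other, 2793, was the split that set the daf-9 mutant apart. Splits that mixed the genotypes called 0 rows, but genotype differences then enter their spread, so they are no measure of noise alone. For the F test 1 of 100 drawn splits, the real one, reached 9548, with 4182 as the highest other, a share under 0.05 with the same limit.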

How the results depend on the processing

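No test of this section on processing was chosen only after the result was seen. Of 267 recomputed main values, 254 kept their direction and stayed within 1.5 times or on their side of the threshold. Without moderation of the variance, 5504 rows were called for both mutants together against wild type and 3198 in the overlap of the 2 mutants against wild type. That test also took the spread from the compared arrays alone. For both mutants together it held them as a single group, so their difference entered the spread. On the simulated data it recovered 24% of 1.5-fold changes in the daf-9 mutant, against 96% with the main fit. The part of each in the lower counts was not tested. A 2-fold minimum, which by construction keeps fewer, left 837 for the daf-9 mutant against wild type, 239 for the daf-12 mutant against wild type, 272 for the daf-12 mutant against daf-9 mutant, 304 for both mutants together against wild type and 1009 for any difference among the 3 genotypes. Gene lists called were 5, 10 and 10 in these comparisons with an estimated correlation, a drop whose cause was not tested, and 31, 30 and 31 with fry, which does not set a list against other genes. Leaving out each array in turn gave 7062 to 7916, 6658 to 7618 and 3709 to 4571 called rows and 4554 to 4905 in the overlap. Of 8986 recomputed values of named genes, 8717 stayed on their side, 200 lost the call, 68 gained it and 1 reversed: din-1 in the daf-9 mutant against wild type went to 0.0522 (adjusted p = 0.44) with rows of a gene averaged, which merges rows of different direction. Of 2052 list values, 1955 stayed, 36 lost the call, 61 gained it and 0 reversed. Without the dimmest 25% of rows the SKN-1 and phase II detoxification list lost its call in the daf-9 mutant (adjusted p = 0.179), as did the infection response genes not dependent on p38 in the daf-12 mutant (0.0548), and both calls were also lost with an estimated correlation (0.0846 and 0.0865). Between the mutants, the dauer and insulin signalling list lost its call without daf-12 mutant replicate 2 (0.0622), and the glyoxylate list lost its own there too (0.0520), under 4 other settings, up to 0.0765, and with an estimated correlation (0.128). Neither scaling alternative moved the share of higher calls by over 10 percentage points, but between the mutants both turned the small majority, from 2298 higher and 2107 lower to 2148 and 2275 with a second quantile normalization and 2123 and 2356 with arrays centred on their medians. With the replicate block, 7984, 7638 and 4418 rows were called and 5326 in the overlap. The replicate numbers do not pair the arrays by any label, and deviations of same-numbered arrays correlated at -0.05 to 0.09, while 8 of 9 arrays correlated best with their own number, a hint from the data alone. The slide block was not run, since no slide was given. Levels near 100 limit what can be said of dim genes.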

Other observations

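The gene groups here were chosen for description only after the result of each test was seen. The transcription factor gene lin-29, needed for the larval-to-adult switch of the skin, fell in the daf-9 (-0.54) and the daf-12 mutant (-0.55), and so did dre-1 (-0.57 and -0.69). The gene lin-41, which acts before lin-29 in this pathway, rose in both (0.57 and 0.51). It also belongs to the oocyte and eggshell list, most of which rose in both mutants. In RNA of whole animals its rise therefore cannot be assigned to the skin. Of 13 heterochronic genes, 4 rose and 3 fell in the daf-9 mutant, and 3 rose and 4 fell in the daf-12 mutant. The list was called in neither (camera adjusted p = 0.96 and 0.68).

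Genes of steroid hormone synthesis and DAF-12 partners fell in 6 of 11 in the daf-12 mutant, but the list was not called (camera adjusted p = 0.056). Among them were dhs-16 (-0.96), the sterol transporter ncr-1 (-0.50) and the mutated gene daf-12 itself (-0.37). The fall of din-1 was lost with rows of a gene averaged (-0.02, limma adjusted p = 0.80). In the daf-9 mutant 4 fell, including strm-1 (-0.69), and daf-12 alone rose. Of dauer TGF-beta and insulin signalling genes, 6 of 17 were lower in the daf-12 than in the daf-9 mutant (camera adjusted p = 0.038), a call lost with an estimated correlation (adjusted p = 0.11). They included the TGF-beta ligand daf-7 (-0.72) and the insulin-like daf-28 (-0.48). Autophagy and lysosome genes were lower in 5 of 19 between the mutants, with sqst-1 at -0.51, and this call was also lost with an estimated correlation (camera adjusted p = 0.018, and 0.13 as the adjusted p with an estimated correlation). Antimicrobial peptide families were not called in either mutant (camera adjusted p = 0.79 and 0.59).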
